A study of Mus musculus with 6 samples.

How the data were processed

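PolyA RNA of the mouse embryonic stem cell line TT-FHAgo2 was measured by strand-specific sequencing in 2 libraries with doxycycline (2.5 µg/mL for 48 h) and 2 libraries taken off it for 96 h. The FPKM values per isoform were made by the authors with TopHat2 2.0.9 and Cufflinks 2.1.1 on build NCBIM37, per the submitters' processing notes. The library total behind the scaling of the FPKM is not stated. The isoforms are those of a Cuffmerge assembly of Cufflinks transcripts with Ensembl transcripts, as the deposited annotation shows. Coordinates of exons were used as the authors deposited them in that annotation, counted from 1 on NCBIM37. The 4-library table and a table of the 2 doxycycline libraries were each deposited as identical copies. The shared values of the 2 tables differed in 5447 of 362054 cases, by at most 0.480%. In the table of all libraries, 25 gene symbols (236 isoforms) had been turned into dates, as a spreadsheet does, and were restored from the other table.

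Of 181027 isoforms, 31251 had no gene name and 8207 named isoforms were left out for their length or class. The 141569 isoforms used were at least 200 nt long and, per the deposited annotation, matched or shared a splice junction with a named transcript, and they belong to 31879 genes. Symbols came from the transcript identifier (126777 isoforms), the file's symbol (14310), an older symbol (1540) or, unmatched, as the file gave them (7149). The length minimum was chosen after the files were seen, because isoforms under 200 nt held between 98.9% and 99.6% of the summed FPKM of a library. The isoforms used summed to 0.509 M and 0.535 M FPKM with doxycycline and 0.449 M and 0.485 M without. The 2 libraries of a condition carry the numbers 0 and 1 in the files. The labels' replicate numbers could not be matched to them, so each condition's libraries were treated as unpaired.

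FPKM was summed per gene and transformed as log2(FPKM + 0.5). Genes with a mean of at least 1 FPKM in either condition were tested with limma 3.58.1 (trend, 2 residual and 3.10 prior degrees of freedom) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 13268 genes at 0.05. Gene lists of at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Fry tests whether a list's genes move on balance and passed 15 of 22 lists. Camera at an estimated correlation rests on the 2 residual degrees of freedom and has little power here. A call lost there does not show that a list is unchanged. Each list's median was also placed among 10000 random lists drawn within 20 bins of mean expression. The lists (23), microRNA families (17, of which 5 are controls from other tissues), tests, alternatives listed at the start and the rule for named genes were fixed before the data were examined. The rule took the 4 Argonautes and the 4 measured members of each list with the largest absolute change (all members for the targets of miR-290 and miR-302). It also took the 10 largest rises and 10 largest falls among genes with at least 5 FPKM in the higher condition that passed limma in the same direction in both numbers, and, under the same conditions, the 5 largest rises among genes with an 8mer of the miR-291a-3p family. Predicted models, pseudogenes and small RNAs were left out of the rises and falls. It named 113 genes, and 1 of the largest rises is not reported here.

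Seed sites were searched in the longest annotated 3′ untranslated region of each symbol in GENCODE mouse release 21, used for names and sequences only. A region was annotated for 21157 symbols, 11504 of them tested. Sites of 8 bases (8mer), 7 bases (7mer-m8, 7mer-A1) and 6 bases (6mer) were told apart, and a gene was assigned to its best site. Further lists were drawn within 10 bins each of expression and length of the region, or within 5 each for the comparison of site types. Heptamers held by at least 50 genes were ranked by the standardised shift of their genes after linear and quadratic trends were removed. Read steps were fitted to FPKM times length of transcripts of at least 500 nt that are their gene's only isoform, at values of 1 to 6 reads. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

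Each procedure was tested on simulated data, and the step search was corrected after its test, which left its values for the real libraries as they were. With 200 of 13268 genes changed, limma called 30% of changes of 0.5 and 96% of changes of 1 on the log2 scale, and 13.9% of its calls were false. With many genes changed, each by at least 0.5, it called 89.1% of changes of 0.5, and 2.88% of its calls were false. Most of these simulated changes were of 1 or more, whereas the median absolute log2 change of the genes called in the data was 0.61. Neither the 89.1% nor the 2.88% therefore carries over to the data. Camera gave p under 0.05 for 7 of 100 unchanged sets and for 20 of 20 sets shifted by 0.5. In that simulation no gene outside the set changed and genes varied independently, so neither rate carries over to the data. Of 100 unchanged lists of 100 genes 6 fell outside the central 95%, and 98 of 100 such lists shifted by 0.3 lay above it. The fixed lists have at most 28 measured members, so this power does not carry over to them. For the 6 mesendoderm genes the central 95% ran from -0.52 to 0.70. The heptamer scan placed 5 of 5 heptamers planted with a shift of 0.3 among the first 10. The shifts of the families' sites read below were smaller, so recovery at their size was not tested. The step search found 99.96% of the true step.

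Alternatives were the pseudocount (0.1 and 1), equal condition medians, the most abundant isoform, no filter, a minimum of 5 FPKM, TPM over all isoforms, a term for the library number and leaving out each library, where a lone library is assumed to vary like the others. For the sites they were other site definitions and matching. All named isoforms, TPM over isoforms of at least 200 nt and lists matched on A and U content were added after the data were seen. The 2 spike-in samples were not analysed here, and quantification status and confidence limits were not used here.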

Results

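PolyA RNA was sequenced from TT-FHAgo2, a clonal mouse embryonic stem cell line in which doxycycline sets the expression of Argonaute 2 (Ago2), the protein that carries microRNAs to their target transcripts. The cells were kept in 0.1 µg/mL doxycycline. They were then raised to 2.5 µg/mL for 48 h, which the labels describe as giving wild-type Ago2, or taken off the drug for 96 h. Each condition had 2 strand-specific libraries, made by what the labels call the UTP method. Values were deposited as FPKM (fragments mapped to a transcript, scaled by its length and by the library total) for each assembled isoform. FPKM was summed per gene, errors are SD over n = 2 libraries, and each log2 change is the value without minus the value with doxycycline on the log2(FPKM + 0.5) scale, which understates the change of genes with low values. The other 2 samples of the series, an embryonic and a mesenchymal stem cell library with spike-in RNA, were not analysed here.

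The depth of a library could be read from the steps between low FPKM values in some columns. The libraries with doxycycline and without it that carry the number 1 stepped in whole reads in 100% of the low values examined, within 0.1 read, where chance gives 20%. Their steps correspond to totals of 46.5 M and 46.9 M fragments (M, mega). In the libraries with the number 0 only 33.1% and 33.9% of the values were whole, so their depth is unknown. At the measured steps, 3 reads on a transcript of 2000 nt are worth 0.0355 and 0.0351 FPKM. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

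The comparison asked how the transcriptome differs when Ago2 expression is withdrawn, in a study of microRNA and target concentrations and of competition between targets for microRNAs. The gene under control was read first, since it checks the labels. Ago2 (chromosome 15, 72926267 to 73015812, minus strand, build NCBIM37) stood at 35.9 ± 0.996 FPKM with doxycycline and 28.7 ± 0.112 without. This fall of -0.32 (SE 0.08) passed the threshold in limma (adjusted p = 0.0293). Of its 5 assembled isoforms, the 3303-nt form measured 15.9 ± 3.86 FPKM with doxycycline and 10.6 ± 2.48 without, and a 14320-nt form 14.3 ± 1.26 and 12.5 ± 1.64. A 14199-nt form measured 3.05 ± 1.37 FPKM with doxycycline and was listed at 0 without it, and a 13691-nt form measured 2.69 ± 0.333 and 5.59 ± 0.733 FPKM. Ago3 (chromosome 4, 126008948 to 126145878, minus strand), another Argonaute, fell from 19.3 ± 1.43 to 6.85 ± 0.811 FPKM (log2 change -1.43, SE 0.12, limma adjusted p = 0.00248). Among its isoforms, a 625-nt form stood at 8.02 ± 0.798 and 1.84 ± 0.368 FPKM with and without doxycycline, a 3472-nt form at 2.16 ± 0.615 and 0.686 ± 0.519, a 15847-nt form at 2.92 ± 0.890 and 0.862 ± 0.110, and a 15595-nt form at 2.06 ± 0.153 and 2.02 ± 0.0532. Ago1, which the assembly places in the same overlapping locus as Ago3, was listed at 0 in every library for each of its 9 isoforms. The values do not tell whether Ago1 RNA is absent from these cells or its reads were assigned elsewhere. The sharing of reads between these genes is therefore uncertain. Ago4 stood at 0.541 ± 0.00407 and 0.605 ± 0.0485 FPKM, below the minimum for testing. The Ago2 call was lost when any 1 of the 4 libraries was left out (limma adjusted p = 0.136 and 0.207 without the doxycycline libraries numbered 0 and 1, 0.0908 and 0.0779 without the others), with the medians of the conditions set equal (0.0547), with TPM (transcripts per M) over isoforms of at least 200 nt (0.146) and with the most abundant isoform alone (0.413). Over 13 alternatives its adjusted p in limma ranged from 0.00626 to 0.413. Ago2 RNA was lower in both libraries without doxycycline than in either with it, by a small amount, and the files do not separate transgene from endogenous transcripts.

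Lefty1 (chromosome 1, 182865142 to 182868531, plus strand), a secreted inhibitor of Nodal signalling, rose from 34.2 ± 2.64 FPKM with doxycycline to 233 ± 4.90 FPKM without it. Its neighbour and paralog Lefty2 rose from 25.3 ± 1.63 to 138 ± 13.8 FPKM, and the split of shared reads between these similar genes is uncertain. The water and glycerol channel gene Aqp3 rose from 9.89 ± 0.635 to 77 ± 1.56 FPKM. In the other direction, the trypsin inhibitor gene Spink1 fell from 73.3 ± 3.39 to 6.01 ± 1.13 FPKM, and Lin28a (chromosome 4, 133559047 to 133574756, minus strand), which encodes an RNA-binding protein that blocks let-7 maturation, from 125 ± 4.85 to 14.2 ± 0.771 FPKM.

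The rises that ranked highest among genes reaching 5 FPKM, leaving out predicted models and small RNAs, ran from Zbp1 (log2 change 3.08), a sensor of Z-form nucleic acid, to the metalloproteinase gene Mmp23 (2.6). Between them were Trim47 (3.03), Megf11 (2.95), Aqp3 (2.90), Chit1 (2.90), Tspan1 (2.77), Lefty1 (2.75) and the lysosomal amidase gene Naaa (2.72). The 10 largest falls by the same rule ran from Spink1 (-3.51) and Lin28a (-3.09) to Kdelr3 (-2.07) and Glipr2 (-2.07), with the growth-cone gene Gap43 (-2.85), Steap1 (-2.62), Tmem150a (-2.50), B3gnt5 (-2.44), Mef2b (-2.34) and Ubap1l (-2.21) in between. All of the genes named here passed the limma threshold, with adjusted p from 0.00147 for Spink1 to 0.00235 for Mmp23, and all moved the same way in both numbered pairs of libraries.

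Of 13268 genes with at least 1 FPKM in either condition, 5351 passed the limma threshold (adjusted p under 0.05). Of these, 2578 were higher and 2773 lower without doxycycline, and 607 rose and 282 fell by at least 1 on the log2 scale. The median absolute change of the called genes was 0.61, and the median of all genes -0.06. Called genes were split 48.2% higher in the FPKM as deposited. The split moved to 57.2% when the condition medians were set equal and to 67.8% (3955 higher, 1876 lower) with TPM over isoforms of at least 200 nt, where the median of all genes was 0.10. Small changes are therefore relative to the scaling. The groups did not overlap for 9693 genes (73.1%), where chance gives 33.3%; for a single gene, a permutation test of 2 against 2 libraries cannot go below p = 0.333. The most abundant isoform alone gave 2023 calls, and leaving out 1 library gave 3354 and 3118 without the doxycycline libraries numbered 0 and 1, and 3585 and 4237 without the others numbered 0 and 1. The lower genes numbered 1630 and 1345, and 1609 and 2405, in the same order.

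The libraries of each condition also differed by their number, in steps and in level. Same-numbered libraries were therefore compared by themselves. Each of the 5351 called genes had the same sign in the 2 numbers, which is nearly a condition of passing the test. Lefty1 rose by 2.81 in number 0 and 2.70 in number 1, and Cdkn1a by 2.34 in each. The log2 ratios of Ago2 were -0.29 and -0.34, and those of Lin28a -3.08 and -3.11.

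**Figure D1:**
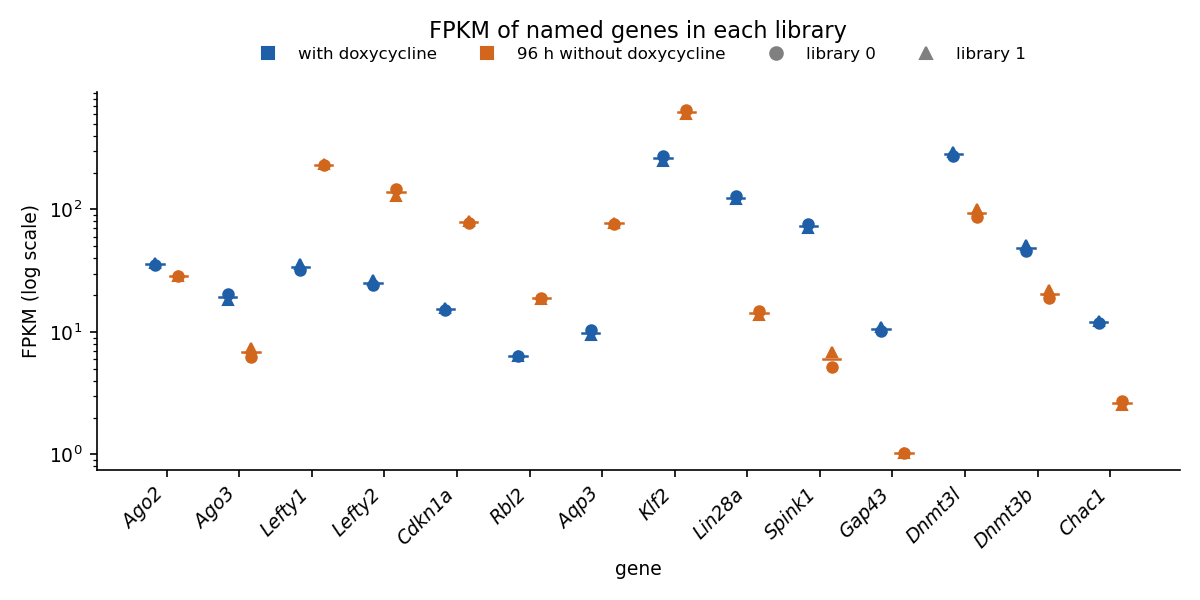
FPKM of 14 named genes on a log scale, with 1 point per library (circle, number 0; triangle, number 1) and a bar at the mean of each condition. Lefty1 lies at 34.2 with and 233 without doxycycline on average, Lin28a at 125 and 14.2, and Ago2 at 35.9 and 28.7.

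Reported targets of the miR-290 and miR-302 clusters, whose microRNAs are abundant in embryonic stem cells, rose as a group. Of 20 measured members, 16 were higher, 0 lower and 4 did not pass, the same counts when adjusted over the list alone. Besides the Lefty genes, Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose from 15.3 ± 0.398 to 79.5 ± 1.92 FPKM. The retinoblastoma relative Rbl2 rose from 6.39 ± 0.0137 to 18.8 ± 0.218 FPKM and the Hippo kinase gene Lats2 from 2.13 ± 0.188 to 6.59 ± 1.25 FPKM. Irf2 went from 0.0946 ± 0.0317 to 2.75 ± 0.237 FPKM and Nr2f2 from 0.232 ± 0.0784 to 1.89 ± 0.424 FPKM. Ei24 (log2 change 1.06), Mbd2 (0.93), Zbtb4 (0.92), Casp2 (0.72), Rbl1 (0.52), Rela (0.50), Wee1 (0.48), Akt1 (0.35) and Rhoc (0.33) were the other members that rose. Arid4b (0.33), Fbxl5 (0.10), Hdac4 (0.06) and Tusc2 (-0.27) did not pass the limma threshold (adjusted p = 0.125, 0.461, 0.751 and 0.370). The list's median change was 0.82, above all of 10000 random lists matched on expression (percentile 100), with medians of 0.73 and 0.87 in numbers 0 and 1, and 0.52 at a minimum of 5 FPKM. Camera, limma's competitive set test with a preset correlation of 0.01, gave an adjusted p of 1.35e-07. With an estimated correlation the call was lost (adjusted p = 0.48).

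Targets of the miR-17/92 cluster, some members of which share part of their seed with the former clusters, included 8 members that rose and 0 that fell among 17 measured; adjusted over the list alone these were 8 and 1. Phlpp2, an Akt phosphatase gene, rose from 3.67 ± 0.0553 to 9.38 ± 0.437 FPKM, and the matrix protein gene Thbs1 from 0.394 ± 0.00974 to 1.38 ± 0.304 FPKM. Cdkn1a, Rbl2 and Zbtb4 belong to this list too. The list median was 0.48 (percentile 99.98, camera adjusted p = 0.00702; adjusted p = 0.48 with an estimated correlation), with 0.30 and 0.55 in the 2 numbers. The median was 0.25 without the library off doxycycline numbered 1, 0.25 with the most abundant isoform and 0.18 at a minimum of 5 FPKM. Among 22 measured let-7 targets, 3 rose and 5 fell, also when adjusted over the list alone. Lin28a and Myc fell, Myc from 17.7 ± 0.981 to 6.52 ± 1.48 FPKM, Hmga1 fell from 87.9 ± 11.5 to 54.1 ± 7.95 FPKM, and Plagl2 rose from 5.53 ± 0.305 to 13.3 ± 0.198 FPKM. The median of this list was -0.02 and its mean -0.19, at percentile 77.7 of random lists by the median (camera adjusted p = 0.614), and the median ran from -0.72 to 0.14 over 14 alternatives. Camera passed the list in 1 of them, TPM over all isoforms (adjusted p = 0.00522, median -0.72), where 5 members were left.

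Genes of the p53 and apoptosis list were higher without doxycycline in 13 of 23 cases, with 1 lower, also when adjusted over the list alone. Btg2, an antiproliferative p53 target, rose from 8.69 ± 0.777 to 30.1 ± 1.64 FPKM and the membrane protein gene Perp from 9.17 ± 0.945 to 20.4 ± 1.59 FPKM, beside Cdkn1a and Casp2. These last 2 genes are also listed targets of miR-290 and miR-302, and Bcl2l11, which rose too, of miR-17/92, so the p53 list is not independent of those. The median was 0.37 (percentile 100, camera adjusted p = 0.00702; adjusted p = 0.48 with an estimated correlation), with 0.35 and 0.42 in the numbers. With TPM over all isoforms, where the median of all genes tested was -0.57, the median of this list was -0.24. In the G1/S list 9 of 25 members rose and 4 fell, also when adjusted over the list alone. Of its members that rose, Cdkn1a, Rbl1, Rbl2 and Wee1 are also listed targets of miR-290 and miR-302, and E2f2 of miR-17/92. The G1/S list is therefore not independent of the target lists. The inhibitor gene Cdkn2b rose from 1.96 ± 0.0322 to 4.37 ± 0.508 FPKM and E2f2 from 2.85 ± 0.0859 to 5.34 ± 0.469 FPKM. That list's median of 0.18 missed the camera threshold (adjusted p = 0.0728), at percentile 99.6, passed it without a filter on low values (0.0272), and ran from -0.62 with TPM over all isoforms to 0.34.

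Transforming growth factor β signalling genes rose in 9 of 19 cases and fell in 2; adjusted over the list alone these were 10 and 2. The 2 that fell were the BMP ligand gene Bmp4, which went from 9.08 ± 1.00 to 2.84 ± 0.353 FPKM and the BMP target Id3, from 24.9 ± 0.234 to 12.8 ± 0.231 FPKM, whereas Id1 and Id2, chosen for mention after their values were seen, stood at changes of 0.02 each and did not pass. Nodal itself and the receptor and Smad genes Acvr1b, Acvr2b, Bmpr2 and Smad3, chosen in the same way, were among those that rose. The others were Lefty1 (log2 change 2.75), Lefty2 (2.42), Skil (0.48) and Ski (0.46). Lefty1 inhibits Nodal signalling, and both Lefty genes are also in the list of miR-290 and miR-302 targets, so the 2 lists are not independent. The median was 0.33 (percentile 99.8, camera adjusted p = 0.0155; adjusted p = 0.48 with an estimated correlation). The preset call was lost without the library with doxycycline numbered 1 (camera adjusted p = 0.0543) and with the most abundant isoform, where the median was 0.16 (0.0592), in a range from 0.00157 to 0.0592 over 13 alternatives, with medians up to 0.50. Of the 6 mesendoderm genes measured, 5 rose and 1 fell, also adjusted over the list alone. Evx1 (0.431 ± 0.113 to 1.79 ± 0.00965 FPKM), Gsc (0.312 ± 0.0125 to 1.28 ± 0.0215), Kdr (0.419 ± 0.0331 to 1.39 ± 0.116) and Col4a1 (6.05 ± 0.641 to 12.5 ± 0.773) were among those that rose, and Evx1, Gsc and Kdr stayed below 2 FPKM. The median was 1.01 (percentile 99.8, camera adjusted p = 0.0263; adjusted p = 0.48 with an estimated correlation). Camera passed the list in 8 of 12 alternatives (adjusted p from 0.0139 to 0.657) and missed it with a term for the library number (0.0746), and without a filter on low values its 21 members had a median of 0.08.

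**Figure D2:**
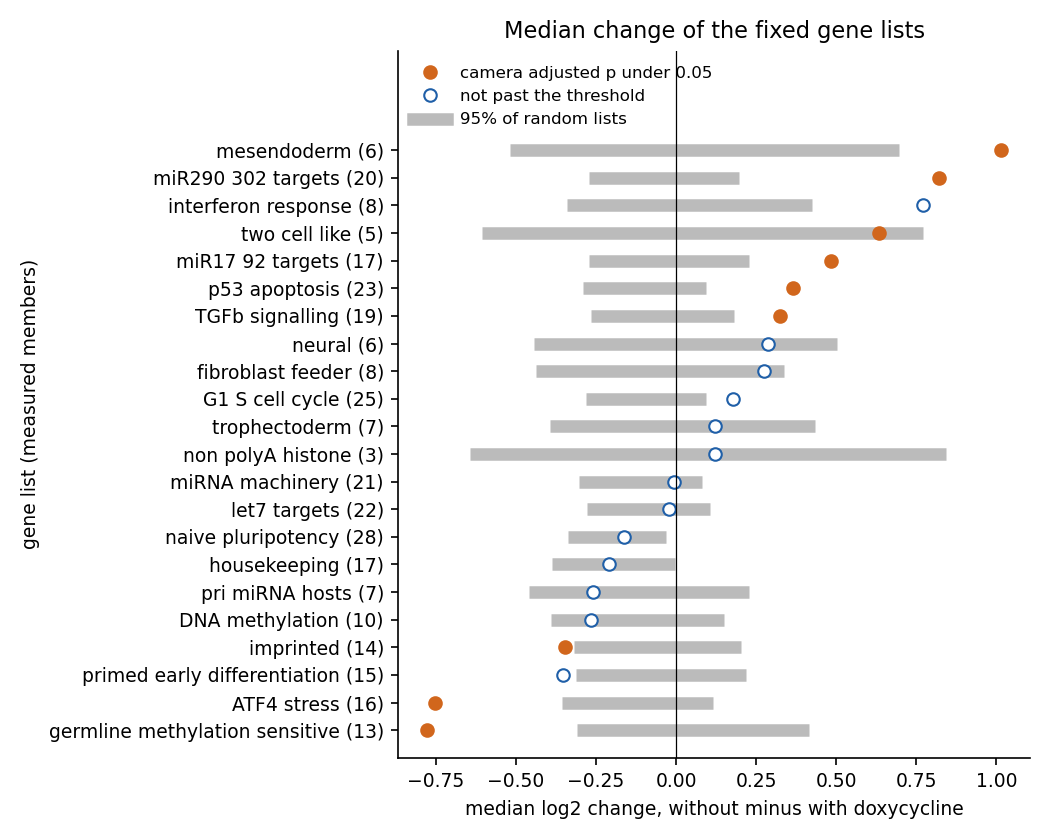
Median log2 change of each of the 22 gene lists with at least 3 measured members (points), against the central 95% of medians of 10000 random lists of matched expression (grey bars). Filled points passed camera with its preset correlation; the list of miR-290 and miR-302 targets lies at 0.82 and the germline list at -0.78.

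Genes of the ATF4 stress list, which holds amino acid synthesis and transport genes, fell in 10 of 16 cases and rose in 2; adjusted over the list alone these were 12 and 2. Chac1, a glutathione-degrading enzyme gene, fell from 12 ± 0.286 to 2.61 ± 0.148 FPKM, and Phgdh, the first enzyme of serine synthesis, from 52.0 ± 7.75 to 20.3 ± 1.08 FPKM. Trib3 fell from 32 ± 1.30 to 14.5 ± 1.48 FPKM and Vldlr from 2.49 ± 0.776 to 0.836 ± 0.318 FPKM. The members that rose, Hspa5 (log2 change 0.35) and Xbp1 (0.49), act in the endoplasmic reticulum branch of the response. The median was -0.75 (percentile 0, camera adjusted p = 0.00936; adjusted p = 0.48 with an estimated correlation), with -0.65 and -0.69 in the 2 numbers. Camera passed the list in 12 of 14 alternatives (adjusted p from 0.00155 to 0.157) and missed it at a minimum of 5 FPKM (0.0574) and with TPM over all isoforms (0.157).

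Among germline genes known to depend on DNA methylation, 9 of 13 were lower without doxycycline and 1 was higher; adjusted over the list alone these were 9 and 2. Sycp3, a synaptonemal complex gene, fell from 3.82 ± 0.454 to 1.23 ± 0.507 FPKM, Tex19.1 from 27.7 ± 0.953 to 12 ± 0.532 FPKM, Taf7l from 1.31 ± 0.0796 to 0.408 ± 0.0319 FPKM and Stk31 from 2.70 ± 0.177 to 1.23 ± 0.118 FPKM. The median was -0.78 (percentile 0, camera adjusted p = 0.0155; adjusted p = 0.48 with an estimated correlation). Camera passed the list in 10 of 13 alternatives (adjusted p from 0.00319 to 0.767) and missed it with a term for the library number (0.0548), with the most abundant isoform (0.0929) and at a minimum of 5 FPKM (0.767), where 5 members were left, with a median of -0.11. Of 10 genes of DNA methylation itself, 2 rose and 4 fell, also adjusted over the list alone, with no call for the list (median -0.27, from -0.59 to -0.11 over 14 alternatives, camera adjusted p = 0.383). The methyltransferase cofactor gene Dnmt3l fell from 286 ± 14.5 to 93.6 ± 9.17 FPKM and Dnmt3b from 48.4 ± 3.75 to 20.5 ± 2.29 FPKM. The demethylase gene Tet3 rose from 1.72 ± 0.0745 to 3.65 ± 0.0637 FPKM.

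Imprinted genes were lower in 7 of 14 cases and higher in 1; adjusted over the list alone these were 9 and 1. Phlda2 fell from 15.8 ± 0.197 to 4.48 ± 0.497 FPKM and the noncoding RNA H19 from 52.2 ± 1.08 to 17.0 ± 2.21 FPKM, while Plagl1, a zinc-finger gene, rose from 12.2 ± 0.880 to 50.4 ± 5.64 FPKM. Snrpn fell by 1.30 on the log2 scale, and its sum is uncertain because it overlaps other transcripts. The median was -0.35 (percentile 1.39, camera adjusted p = 0.0155; adjusted p = 0.48 with an estimated correlation). Camera passed the list in 12 of 14 alternatives (adjusted p from 0.00218 to 0.0591) and missed it at a minimum of 5 FPKM (0.0574) and with TPM over all isoforms (0.0591), and the median ran from -0.85 to -0.16. Peg10, another member, is not among the 14, because the files hold the locus at its place without a gene name. In the list of microRNA host transcripts, 3 of 7 fell and 0 rose; adjusted over the list alone these were 4 and 0. Mir17hg, the host of the miR-17/92 cluster, went from 24.5 ± 3.61 to 14.4 ± 2.82 FPKM and Mir22hg from 2.63 ± 0.0969 to 1.17 ± 0.0893 FPKM. This list did not pass (median -0.26, from -0.49 to -0.06 over 14 alternatives, camera adjusted p = 0.139).

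Pluripotency genes moved both ways. Of 28 measured, 6 rose and 10 fell, also adjusted over the list alone, and the list did not pass (median -0.16, from -0.47 to -0.00442 over 14 alternatives, percentile 64.8, camera adjusted p = 0.479). Klf2 rose from 261 ± 16.7 to 625 ± 40.7 FPKM and Prdm14 from 9.66 ± 0.453 to 21.7 ± 0.800 FPKM, whereas Dppa3 fell from 8.12 ± 1.84 to 3.01 ± 0.291 FPKM. Of 15 genes of the primed state and early differentiation, 5 rose and 7 fell, also adjusted over the list alone. Their median was -0.35 and their mean 0.10, so these differ in sign, and camera, which went with the median, gave an adjusted p of 0.669. The median lay at percentile 1.32 of random lists, and at 0.48 with matching on transcript length as well, and was -0.13 without the library off doxycycline numbered 1, -0.21 both without a filter on low values and at a minimum of 5 FPKM, and -0.20 with TPM over isoforms of at least 200 nt. Pou3f1 fell from 2.56 ± 0.185 to 0.898 ± 0.166 FPKM, beside the fall of Dnmt3b and the rise of the Lefty genes.

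Markers of other cell types and states were read in the same way. In the neural list 2 of 6 rose (3 adjusted over the list alone) and 0 fell (median 0.29, from 0.02 to 0.45 over 12 alternatives, camera adjusted p = 0.203), with Nes at 2.17 ± 0.131 and 4.63 ± 0.364 FPKM and Ncam1 at 8.36 ± 1.09 and 12.1 ± 1.95. Trophectoderm markers rose in 2 of 7 cases and fell in 2, or 3 and 2 adjusted over the list alone (median 0.12, from 0.01 to 0.39 over 13 alternatives, camera adjusted p = 0.522). Krt8 rose from 9.85 ± 1.51 to 26.5 ± 5.39 FPKM and Ascl2 fell from 2.46 ± 0.0490 to 0.498 ± 0.161 FPKM. Fibroblast and feeder markers rose in 2 of 8 cases and fell in 1, or 3 and 1 adjusted over the list alone (median 0.27, from 0.10 to 0.50 over 13 alternatives, camera adjusted p = 0.329). Vim, at 102 ± 24.3 and 209 ± 92.7 FPKM, did not pass in limma (adjusted p = 0.0735), Fn1 rose by 0.47, and Loxl1 fell from 1.91 ± 0.0694 to 0.800 ± 0.181 FPKM. Of 5 measured markers of the 2-cell-like state, 4 rose and 0 fell, also adjusted over the list alone (median 0.63, percentile 94.8, camera adjusted p = 0.0430; adjusted p = 0.48 with an estimated correlation). These were Zscan4f (3.28 ± 0.978 to 6.21 ± 0.320 FPKM), Zscan4c (1.52 ± 0.229 to 2.88 ± 0.125), Sp110 and Usp17lc, of which the Zscan4 copies share reads and are uncertain. Zscan4b, Zscan4d and Zscan4e, also members, are not among the 5, because the loci at their places carry no gene name. The preset call was lost without either library off doxycycline (camera adjusted p = 0.0586 without number 0 and 0.0603 without number 1) and with a term for the library number (0.0897), and it held in 6 of 12 alternatives (0.00279 to 0.0897).

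Interferon response genes rose in 5 of 8 cases and fell in 2, or 6 and 2 adjusted over the list alone. Irf9 rose from 5.46 ± 1.2 to 18.6 ± 0.990 FPKM, Irf1 from 7.04 ± 0.240 to 20.5 ± 1.68 FPKM and Oas1a from 6.82 ± 0.0467 to 16 ± 1.95 FPKM, and Bst2 fell from 43.9 ± 5.07 to 16.7 ± 2.56 FPKM. The median of 0.77 lay at percentile 99.95, and camera gave an adjusted p of 0.0555. It was 0.0320 and 0.0403 without the library with doxycycline numbered 0 and 1, and from 0.00155 to 0.103 over 13 alternatives (camera adjusted p), and the median was 0.28 without a filter on low values. Of the 21 genes of microRNA processing and silencing, 3 rose and 2 fell, or 3 and 1 adjusted over the list alone. The median was -0.01 (from -0.49 to 0.15 over 14 alternatives), while the mean of 0.10 and camera (adjusted p = 0.614) went upward. The RNA helicase gene Mov10 rose from 54.0 ± 4.53 to 129 ± 13.6 FPKM, and the genes of the Argonaute partners Tnrc6a and Tnrc6b rose by 0.55 and 0.62. Their paralog Tnrc6c, also in the list, stood at -0.03 and did not pass (limma adjusted p = 0.780). Housekeeping genes included 2 of 17 that rose and 4 that fell, or 2 and 3 adjusted over the list alone (median -0.21, from -0.51 to 0.02 over 14 alternatives, camera adjusted p = 0.628), among them Hprt, which went from 92.9 ± 12.3 to 48.3 ± 8.38 FPKM, and B2m, from 7.98 ± 0.149 to 13.9 ± 0.290 FPKM. Rplp0, at 694 ± 59.0 and 435 ± 70.3 FPKM, shares sequence with pseudogenes and is uncertain. Of 3 measured histone genes that usually lack a polyA tail, 0 passed (median 0.12, from -0.03 to 0.28 over 12 alternatives, camera adjusted p = 0.614). Of the 22 lists tested, 9 passed camera with the preset correlation and 0 with an estimated one, where 1 list had an unadjusted p under 0.05 (targets of miR-290 and miR-302, 0.024). The estimated correlation of that list was -0.00555, below the preset 0.01, so its call was not lost to a larger correlation. The estimate was also below the preset for the transforming growth factor β (-0.0483), mesendoderm (-0.0538) and 2-cell-like (-0.176) lists. It was above the preset for targets of miR-17/92 (0.189) and for the imprinted (0.0957), ATF4 (0.0942), germline (0.0895) and p53 (0.0396) lists. For these, a larger correlation may have contributed to the lost call, and the preset p may be too small. Fry, limma's test of whether a list moves on balance, which makes no comparison with other genes, passed 15.

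Genes with 8mer seed sites for some embryonic stem cell microRNAs in the 3′ untranslated region were on balance higher without doxycycline than genes without such sites. An 8mer site, the longest canonical match, of the family of miR-291a-3p, miR-294-3p, miR-295-3p and miR-302 (AGCACTTA in DNA letters; called here the miR-291a-3p family) was present in 423 of 11504 tested genes with an annotated 3′ untranslated region. Of these, 158 (37.4%) were higher and 46 (10.9%) lower, against 17.6% and 22.6% of the 7541 genes without a site. Their regions were longer (median 2918 against 892 nt). For the control family miR-124, 26.2% of 8mer genes were higher and 14.8% lower, against 18.8% and 22.4% without a site. The median change of the 423 genes was 0.21, where 95% of expression-matched random lists lay between -0.06 and 0.05 (percentile 100). With matching on length of the region as well, 95% of lists lay between -0.02 and 0.08 (percentile 100). In number 0 the median was 0.18 and in number 1 it was 0.19. With TPM over all isoforms the median turned to -0.41 (43 genes), above that of all genes tested (-0.57), and it was 0.09 (573 genes) without a filter on low values and 0.37 with TPM over isoforms of at least 200 nt. Genes with the 8mer of the family of miR-17, miR-20, miR-93 and miR-106 (the miR-17 family, 513 genes) had a median of 0.21 and those with the 8mer of the family of miR-92a, miR-25 and miR-32 (the miR-92a family, 322 genes) 0.14; with TPM over all isoforms these were -0.35 and -0.44, without a filter on low values 0.13 and 0.04, and with TPM over isoforms of at least 200 nt 0.37 and 0.27. Among the 8mer genes that reached 5 FPKM, the highest rises were those of Lefty1, Lefty2, Cdkn1a, the adhesion gene Parva, which went from 4.39 ± 1.41 to 22.0 ± 2.89 FPKM, and Cd109, from 1.47 ± 0.000206 to 7.60 ± 0.975 FPKM.

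The change followed the type of site in the miR-291a-3p family only in part. The median was 0.21 for genes whose best site was an 8mer, 0.06 for 7mer-m8 sites (1686 genes), 0.06 for 7mer-A1 sites (384 genes), 0.05 for 6mer sites (1470 genes) and -0.07 with no site. Set against lists of 7mer-m8 genes matched on expression and length of the 3′ untranslated region, the 8mer genes lay at percentile 100, and the same comparison gave 100 for miR-17 and 99.6 for miR-92a.

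**Figure D3:**
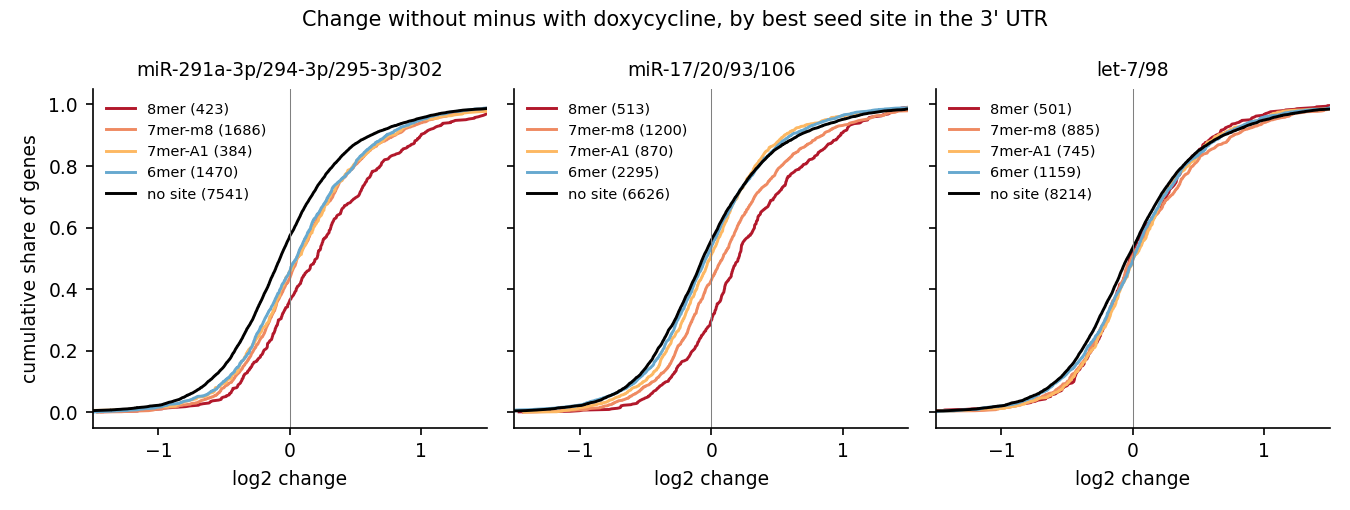
Cumulative share of genes by log2 change for genes grouped by their best seed site in the 3′ untranslated region, for 3 microRNA families (gene numbers in parentheses; the axis is limited to part of the range). In the first panel the 8mer curve lies to the right, with a median of 0.21 against -0.07 with no site, whereas the let-7 curves overlap. The 8mer genes of that panel have longer 3′ untranslated regions than the genes with no site (median 2918 against 892 nt).

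With the preset correlation, camera passed 3 of the 17 families: miR-17 (adjusted p = 2.55e-05), miR-291a-3p (0.000454) and miR-92a (0.00521). With an estimated correlation 0 families passed, the smallest adjusted p being 0.467, and 0 had an unadjusted p under 0.05, while fry passed 8. The estimated correlation was 0.00931 for miR-291a-3p, below the preset 0.01, and 0.0158 for both miR-17 and miR-92a. Percentiles alone were less selective, because 11 of the 17 families and 2 of the 5 control families of other tissues, miR-124 and miR-142-3p, lay above the central 95% of lists. After matching on length of the 3′ untranslated region as well, 8 families and 1 control family, miR-124, did so. The medians of the control families lay between 0.02 and 0.07, and that of let-7/98 was -0.02. In genes with no 8mer or 7mer-m8 sites of the other families of embryonic stem cells, which can still hold their shorter or 7mer-A1 sites, the median was 0.15 (78 genes) for miR-291a-3p, 0.57 (20 genes) for miR-17 and -0.01 (68 genes) for miR-92a.

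A scan of 16232 heptamers in the same sequences asked whether the families' sites stood out, after removing trends with length, base content and expression. The heptamer at rank 1 was GCACTTT, the 7mer-m8 site of miR-17 (1713 genes, shift 0.15). AGCACTT and GCACTTA, both sites of the miR-291a-3p family, ranked 2 and 3 (shifts 0.11 and 0.14), and GTGCAAT, the site of miR-92a, ranked 5 (shift 0.10). The let-7 site CTACCTC ranked 12587 (shift -0.01). Since AGCACTT is part of the 8mer, the scan was run again in the 11081 genes without the 8mer, a step added after the first ranks were seen, and AGCACTT again ranked 2, of 16215 heptamers (1686 genes, shift 0.08). Where a T follows, AGCACTT also holds the miR-17 site.

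**Figure D4:**
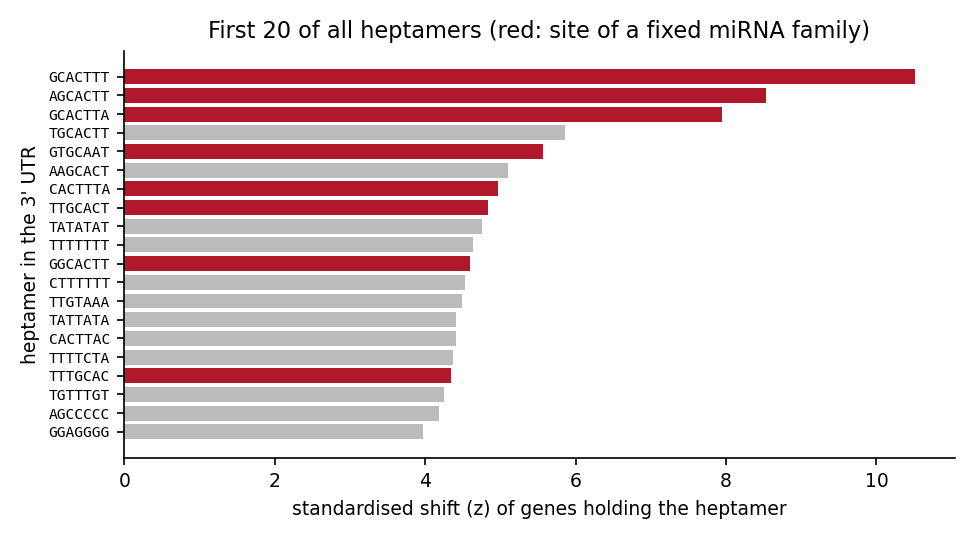
Standardised shift (z) of the genes holding each of the 20 heptamers that ranked highest, out of 16232 scanned; red bars are sites of a fixed microRNA family. GCACTTT (z = 10.5) and AGCACTT (8.53) lead. A single shuffle of the changes gave at most 3.75, which all 20 exceed, also words that are no site of a fixed family, such as TATATAT (4.75) and TTTTTTT (4.64). Passing the shuffle is therefore not particular to seed sites.

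Since the study concerned target concentrations, the transcriptome's supply of sites was summed as FPKM times the number of 8mer, 7mer-m8 and 7mer-A1 sites per gene. For the miR-291a-3p family this pool was 84353 ± 3620.2 with and 83583 ± 4050.0 without doxycycline, a difference within the spread of the libraries (log2 ratio -0.01), while the FPKM of all genes with a 3′ untranslated region had a log2 ratio of -0.14. The 8mer sites made up 11.1% of the pool with doxycycline and 12.4% without, and 7mer-m8 sites 68.7% and 67.4%. With doxycycline, 164 genes held 50% of the pool, and Ncl, the nucleolin gene, held the most at 3.91%. Without it Rpsa held the most, at 2.59%. Sites were counted in the longest annotated region of each gene, which its expressed isoforms may lack, so the pool and its top holders are uncertain. The pool was not converted to copies per cell, since the spike-in libraries were not analysed here.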

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

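Alternatives chosen after seeing the data were all named isoforms, TPM over isoforms of at least 200 nt and lists matched on A and U content; the others were planned. Of 1420 values for named genes under the alternatives 1295 kept their sign and side of the threshold, of 293 list medians 257, and of 320 medians for the other microRNA families 224; the sign changed in 8, 12 and 42, of which 1, 1 and 17 belong to results that had passed. TPM over all isoforms divides by the summed FPKM, which was 123 M in the library off doxycycline numbered 1. It was 48.5 M in the other library off doxycycline and 50.2 M and 54.6 M with it, so this scaling lowers every gene in the former library. TPM over all isoforms tested only 1944 genes, since short isoforms take nearly all of the sum. With it 2 genes passed, 0 higher and 2 lower, and 3 lists passed camera. Its median of all genes was -0.57, and the 8mer medians turned negative: -0.41 for the miR-291a-3p family, -0.35 for miR-17, -0.44 for miR-92a, -0.47 for miR-19, -0.54 for miR-18, -0.57 for miR-130 and miR-301, -0.32 for miR-293-3p, -0.40 for miR-292-3p, -0.61 for miR-21, -0.50 for miR-124 and -0.52 for miR-142-3p, as did Fn1 at -0.0576 and the p53 list at -0.24. In genes without 8mer or 7mer-m8 sites of the other embryonic stem cell families (7mer-A1 and 6mer sites remain) the medians were -0.0126 for miR-92a, -0.0516 for miR-19, -0.0119 for miR-18, -0.0541 for miR-130 and miR-301, -0.0323 for miR-292-3p, -0.0214 for miR-124 and -0.00196 for miR-142-3p, sets of fewer genes; of the families that had not passed, the medians were -0.136 for miR-15 and miR-16 (percentile 0.85), -0.0864 for miR-122, -0.0721 for miR-26, -0.0492 for miR-9 and -0.0190 for miR-1 and miR-206. The most abundant isoform gave 2023 genes (1046 higher, 977 lower) and 5 lists, and a minimum of 5 FPKM 4 lists, for causes that were not tested. TPM over isoforms of at least 200 nt gave 3955 higher. The summed FPKM of these isoforms was 0.531 M and 0.556 M with doxycycline and 0.469 M and 0.504 M without, so this scaling raises every gene off doxycycline. A term for the library number raised the genes to 8123, with 4516 lower, and ended camera's calls of the germline (adjusted p = 0.0548), mesendoderm (0.0746) and 2-cell-like (0.0897) lists. Same-numbered deviations had a correlation of 0.464 across genes, which are not independent replicates. The change of Ago2 was -0.25 with equal condition medians, -0.18 with the most abundant isoform and -0.16 with TPM over isoforms of at least 200 nt, none past limma. Leaving out 1 library gave 3118 to 4237 genes (1724 to 1976 higher, 1345 to 2405 lower), 8 to 10 lists, a miR-291a-3p median of 0.17 to 0.20 and Ago2 changes of -0.35 to -0.29, with limma's calls based on fewer samples. Splits by quantification status and by 95% limits of FPKM were planned and not run, since the tables used here hold no such columns, and a 1.5-fold minimum was planned only for a design without a test. Depth is known for 2 of the 4 libraries, so small changes of genes near 0.0355 FPKM in the others have no stated floor.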

Other observations

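Tests chosen only after the result was seen were the heptamer scan in genes without the 8mer and the reading of the germline genes' direction, the matching on length of the 3′ untranslated region was planned but its bound was set after the result was seen, and the mitochondrial lists were written after the data were seen. In the list for mitochondrial one-carbon and proline metabolism, with no member in the ATF4 list, 4 of 6 genes were lower without doxycycline and 0 higher (median -0.47). Its members Pck2 (log2 change -0.44), counted among the lower, and Slc25a39 (-0.20), which did not pass, belong to neither pathway. Mthfd2, a folate enzyme gene, fell from 73.9 ± 1.22 to 31.8 ± 0.0729 FPKM. Mitochondrial chaperone and protease genes had 2 of 12 lower and 0 higher (median -0.18, percentile 45). Of 12 measured mitochondrially encoded mRNAs 3 were lower and 0 higher (median -0.40, percentile 8.35), and these transcripts carry short tails in polyA libraries.

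The assembly also held 14308 loci of at least 200 nt without a gene name, of which 932 reached 1 FPKM in either condition and 212 of those had more than 1 exon. Of the 932, 53 were higher and 33 lower without doxycycline by at least 2-fold in both numbers, on the log2(FPKM + 0.5) scale and without a test. A 3-exon locus on chromosome 6 (4697306 to 4710517, plus strand), which is the place of the imprinted gene Peg10 in the GENCODE M21 annotation after a shift of 50000 nt between builds, measured 145 ± 9.19 FPKM with and 55.5 ± 0.854 without doxycycline. A 4-exon locus on chromosome 5 (143200532 to 143206801, minus strand) measured 2.86 ± 0.285 and 11.5 ± 0.411 FPKM.

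Genes with 8mer sites of the miR-291a-3p family were higher without doxycycline. Length of the 3′ untranslated region, or the base content of the motif, as the whole cause is argued against, since their median lay at percentile 100 of lists matched on expression and that length and at percentile 100 of the 1390 other orders of the same bases, the highest of which, ACGACATT, reached 0.20 against 0.21. Weaker repression at these sites off doxycycline may account for the rise: the family's 7mer-m8 site ranked 2 of 16232 heptamers in all genes, the 8mer genes included, and 2 of 16215 in the genes that lack the 8mer. Ago2 RNA itself fell by only 0.32, a call that held in 6 of 13 alternatives, and the Ago2 protein was not measured, so these libraries do not show how far Ago2 was withdrawn. Camera's call of the family was not kept with an estimated correlation, but that version rests on 2 residual degrees of freedom and cannot decide here. Genes with a 7mer-m8 as their best site had a median of 0.06, no more than those with a 7mer-A1. Part of the 7mer-m8 sites are shared with miR-17, and the control family miR-124 also lay above its length-matched lists. Weaker repression therefore stays a hypothesis.

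Genes of the ATF4 list were lower without doxycycline. Camera's preset call of the list held in 12 of 14 alternatives, and like all other lists it did not pass with an estimated correlation (adjusted p = 0.48). A trend with transcript length is argued against, since the list's median lay at percentile 0 of lists matched on expression and length. Doxycycline itself, which blocks mitochondrial translation, may raise this response in the treated cells. The mitochondrial one-carbon and proline list, written after the data were seen, lay at percentile 1.44, on the side predicted before the test was run. Any cause that lowers genes linked to ATF4 could give this value, so it cannot single out doxycycline. After a first value (percentile 0.26, 8 genes) was seen, Shmt2 and Aldh1l2, which are also in the ATF4 list, were taken out of the one-carbon and proline list to keep the lists apart. Since one-carbon genes are linked to ATF4, since mitochondrial chaperones and proteases (percentile 45) and mitochondrially encoded mRNAs (8.35) stayed within the central 95% of random lists, and since doxycycline and Ago2 change together, this stays open and a part for Ago2 is not excluded.

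Germline genes sensitive to DNA methylation were lower without doxycycline, as were Dnmt3b and Dnmt3l. Camera's preset call of the list was lost with a term for the library number (adjusted p = 0.0548) and with the most abundant isoform (0.0929). It was also lost at a minimum of 5 FPKM (0.767), where 5 members had a median of -0.11. The list's median lay at percentile 0 of lists matched on expression, the opposite side from a release of silenced genes by lower DNA methylation, but this restates the pattern and is no separate test of it. A trend with transcript length is argued against, with percentile 0 of lists matched on expression and length. DNA methylation was not measured, and most of these genes lie at low FPKM. What lowers them stays open, with Ago2 and doxycycline both untested as causes.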
